A study of Homo sapiens with 8 samples.

How the data were processed

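RNA was sequenced from BT-549 cells carrying an empty vector or PTEN and from MCF7 cells carrying a non-targeting shRNA or an shRNA against PTEN, with 2 samples in each of 4 groups. Per the labels' protocols and the series design, libraries were made with a stranded total RNA kit from RNA with an integrity number of at least 9.5 and sequenced as paired 100-base reads. The series design gives 2 biological replicates per group, each with 2 technical replicates. The submitters' processing notes name CASAVA, STAR and DESeq2 without versions, and the genome build hg19. The counting tool and the gene annotation are not given in the sources used here.

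The values analysed were 2 comparison tables, 1 per cell line, with 1 row per gene and no value per sample. Per the file headers, the authors gave for each gene a mean normalized read count over all libraries of the table, which is a signal with no SD or n here. The authors also deposited a log2 fold change with its standard error, a Wald score, a p-value and an adjusted p-value. Recomputing these from the deposited columns checked that the score was the log2 fold change over its standard error in every row, and that the adjusted p-value was the Benjamini-Hochberg adjustment over the rows that carried one. An adjusted p-value was given for 9450 of 12637 rows in BT-549 and for 9812 of 19785 rows in MCF7, and rows without one were left without a call. Depth per sample was not analysed here, so precision is given only by the deposited standard errors. The direction of each fold change (PTEN over vector, and PTEN shRNA over non-targeting shRNA) was taken from the naming of each deposited table.

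The design fixed before the data were examined foresaw tables without per-sample values, and its branch for that case was used: the authors' deposited statistics were counted at an adjusted p under 0.05. Overlap between the lines was tested with Fisher's exact test, two-sided, among rows with an adjusted p in both tables. The 31 gene lists fixed beforehand were tested with cameraPR in limma 3.58.1 under R 4.3.3, on the deposited Wald score with a preset inter-gene correlation of 0.01, for lists with at least 5 measured members. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. On simulated independent scores, with every member of the largest list shifted, the list test called this 1 planted list and no other in each table. That does not show whether smaller lists or smaller shifts would be called. With 200 rows of the BT-549 table given a log2 fold change of 1 at their deposited standard errors, 94 of the 200 were called among 9450 rows. The step that recovers library units from low values found 8 of 8 simulated units.

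Gene order and gene names came from GENCODE release 29 on GRCh38, matched by unversioned identifier to 12602 rows (99.7%) in BT-549 and 19715 rows (99.6%) in MCF7. Its coordinates set the gene order, the rows taken into each segment and the limit of the short arm of chromosome 18. They also served the search for shifts given below. None is printed, because the labels name hg19. Symbols had been turned into dates in 17 rows of each table, and 24 and 44 rows had no symbol. Because many genes used by every cell had few or no reads, rows were read as the named gene only in chromosome segments where such genes were found at expected levels. This rule was set after the levels, but not the fold changes, had been seen, and its first version (a level of 20 in both tables) was replaced. In its final form, a segment was a run of at least 3 neighbouring genes from a set of 388 ubiquitous genes (ribosomal proteins, proteasome subunits, respiratory chain subunits and similar families), each with a mean normalized count of at least 25 in the higher of the 2 tables. A run was kept if at least 80% of the genes of a second set of ubiquitous families inside it also reached 25. Of 8 runs, 4 were kept, and the rows in them together with those of the mitochondrial genome are called assigned rows (441 in BT-549, 537 in MCF7). Rows elsewhere are referred to by their label only.

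Named genes were chosen by a rule fixed beforehand. In each line it took PTEN, the 8 largest rises and the 8 largest falls past the threshold at a mean normalized count of at least 100, leaving out pseudogenes, small RNAs and clone-named loci. For both lines together it ranked genes at a mean normalized count of at least 100 in both tables by the smaller of their 2 changes, and took the first 8 with opposite changes and the first 4 with changes in the same direction, and for lists up to 4 members each. The restriction of this rule to assigned rows was added after the levels had been seen. Alternatives to the threshold, the fold change, the filter, the adjustment, the centring and the settings of the list test were planned beforehand. Alternatives with larger standard errors, scores recomputed from centred fold changes, other segments and assigned rows only were added after seeing the data.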

Results

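RNA-seq was carried out on 2 human breast cancer cell lines in which PTEN, a lipid phosphatase that opposes PI3K signalling, had been changed in opposite directions. BT-549, a triple-negative line, carried either an empty vector or PTEN. MCF7, an estrogen receptor-positive line, carried a non-targeting shRNA or an shRNA against PTEN. Each of the 4 groups held 2 samples, 8 in all. The title of the series places the comparison in a study of RNA polymerase II occupancy, and the RNA-seq part asks which transcripts change when PTEN is gained or lost. The authors' deposited table for BT-549 held 12637 rows with a summed mean normalized count of 3526268, and that for MCF7 held 19785 rows with a sum of 3998855. Mitochondrial rRNA took 66.3% of the sum in BT-549 and 66.8% in MCF7, and nuclear protein-coding rows took 23.7% and 22.7%. The nuclear rows of the authors' deposited tables thus rested on 1062577 and 1163523 mean normalized counts.

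The number of columns behind the MCF7 table could be read from its lowest values. All 36 distinct values below 3 reads were sums of 2 of 8 library units, and 120 of 120 distinct values of 3 reads were sums of 3 of the same units, within 9e-09. The table therefore averaged 8 columns, against 4 MCF7 samples in the labels, and the highest unit was 1.29 times the lowest. The lowest value of the BT-549 table was 1.17, too high for the same reading. With no values per sample, the p-values below are those of the authors' model, and their spread may include technical replicates. If it does, the deposited standard errors can be too small for 2 biological replicates per group, and the p-values too low. Results with standard errors multiplied by the square root of 2 are therefore given as well for the counts within each line and for named genes. They were not computed for the overlap of the 2 lines or for the gene lists.

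PTEN itself could not be used to check the labels. It had no row in the authors' deposited table for BT-549. In MCF7 the authors' deposited table gave PTEN a mean normalized count of 1.44 and a log2 fold change of 1.60 ± 1.36 (SE), with an unadjusted p of 0.237 and no adjusted p. Other genes that these cells use heavily were also missing or low. GAPDH, TUBA1B, KRT8, KRT18 and HSP90AB1 had no row in either of the authors' deposited tables, and ACTB had mean normalized counts of 17.0 in BT-549 and 12.5 in MCF7. Of 388 genes from ubiquitous families, 221 had no row in BT-549 and 155 had none in MCF7, and 87 (22.4%) reached a mean normalized count of 25 in the higher of the 2 tables.

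Some of the ubiquitous genes that did have reads lay together. Of the 87 at the level, 20 lay in the 4 segments described below and 67 elsewhere, where 18.2% of the ubiquitous genes reached it. Among neighbouring pairs of these genes, 30 had both members at the level, against a mean of 18.2 with the levels permuted (permutation p = 0.001, 10000 permutations). In 4 segments, named here by their first and last ubiquitous gene, levels were those of expressed genes. The segments ran from PSMD13 to POLR2L on chromosome 11, from NDUFS7 to NDUFA11 on chromosome 19, from MRPL36 to MRPS30 on chromosome 5 and from RPS6 to TOMM5 on chromosome 9. Protein-coding genes outside both sets of ubiquitous families, which the rule did not use, reached the level for 233 of 394 genes inside the segments (59.1%) and for 3593 of 17963 genes outside (Fisher's exact test, two-sided, p = 5.29e-63). Genes of the same segment are not independent, and the rule was set after levels had been seen, so this p-value only describes the tables. The share of such genes ran from 52.85% to 71.88% over the kept segments, and from 28.65% to 40.62% over the runs not kept. Gene names are therefore read as genes only in these segments and in the mitochondrial genome, and elsewhere as row labels.

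**Figure D1:**
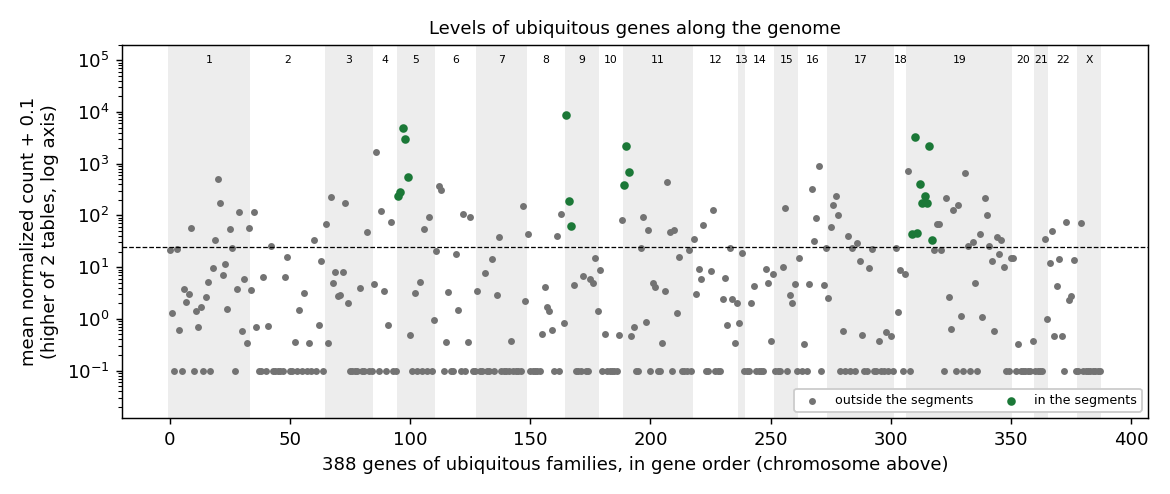
Mean normalized count plus 0.1 (higher of the authors' 2 tables, log axis) of 388 genes from ubiquitous families in gene order, with chromosomes shaded in turn and the level of 25 dashed. Green points are the 20 genes inside the 4 segments, all above the dashed line, and 87 of the 388 genes reach it in all.

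Gain of PTEN in BT-549 was accompanied among the assigned rows by higher levels of CDH6, NPR3, RECK and TPM2 and by lower levels of DDX58, IFITM1 and IRF7. In the authors' deposited table, CDH6 (ENSG00000113361), a cadherin of cell-cell contacts, rose by 3.27 ± 0.22 (log2 fold change ± SE, adjusted p = 4.59e-48). The authors' deposited table also gave rises of 1.89 ± 0.15 for NPR3, the clearance receptor of natriuretic peptides, 1.34 ± 0.14 for RECK, a membrane-anchored inhibitor of matrix metalloproteases, and 1.28 ± 0.06 for TPM2, an actin-binding tropomyosin. Further rises in the authors' deposited table were 1.46 ± 0.12 for the glycosyltransferase gene B4GALNT4, 1.44 ± 0.11 for FAM214B, 1.05 ± 0.14 for MKNK2, a kinase of the translation factor eIF4E, and 0.995 ± 0.103 for the secreted factor MYDGF. Their adjusted p-values in the authors' deposited table lay between 5.79e-89 and 5.49e-13.

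Among assigned rows with a mean normalized count of at least 100, the largest fall in BT-549 was that of DDX58 (ENSG00000107201), which encodes the viral RNA sensor RIG-I, with a log2 fold change of -2.47 ± 0.24 and an adjusted p of 2.49e-23 in the authors' deposited table. The interferon-inducible genes IFITM1 (-1.21 ± 0.25) and IRF7 (-1.21 ± 0.19) followed in the authors' deposited table, while their neighbour IFITM3 was at -0.02 ± 0.06 (adjusted p = 0.873). The list of interferon-stimulated genes fixed beforehand did not pass in BT-549 (cameraPR, adjusted p = 0.248). Of its 8 measured members, 2 passed the threshold as lower, DDX58 and IRF7, and 0 as higher. Among assigned rows at a mean normalized count of at least 100, falls of 0.70 to 0.85 on the log2 scale in the authors' deposited table were those of the tRNA-modifying enzyme gene DUS3L (-0.85 ± 0.12), the nucleolar gene NOL6 (-0.79 ± 0.07), MTRR (-0.78 ± 0.10), which encodes methionine synthase reductase, TUSC1 (-0.71 ± 0.11) and the co-chaperone gene DNAJA1 (-0.70 ± 0.07). Of 368 assigned rows with an adjusted p, 140 passed the threshold in the authors' deposited table, 73 higher and 67 lower with PTEN. Among those open to the rule for named genes, at a mean normalized count of at least 100, 47 were higher and 53 lower. With an absolute log2 fold change of at least 1, 23 were higher and 7 lower, so the balance depends on the setting. Counted over all rows, 2146 of 9450 passed in the authors' deposited table, 1123 higher and 1023 lower. Outside the segments, the row labels with the largest rises at a mean normalized count of at least 100 were APCDD1, PMS1, PROCR, TNIP1, WDR27 and CYP2A7, with log2 fold changes from 1.81 to 5.91 in the authors' deposited table. The largest falls there were those of PCGF5 (-3.14), WASF3-AS1 (-2.32) and KDM2B (-1.93) in the authors' deposited table. With standard errors multiplied by the square root of 2, 79 assigned rows and 984 rows in all passed.

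With the shRNA against PTEN in MCF7, the largest falls among assigned rows with a mean normalized count of at least 100 were those of MATK and GHR, and the largest rises, which were smaller, those of TIMM13 and RUSC2. At that level the authors' deposited table gave the largest falls to MATK, a non-receptor tyrosine kinase gene (-1.09 ± 0.11, adjusted p = 1.28e-20), and GHR, the growth hormone receptor gene (-0.91 ± 0.09, adjusted p = 2.21e-20). Lower levels in the authors' deposited table were also found for the long non-coding RNA TINCR (-0.82 ± 0.13), MLLT3 (-0.73 ± 0.13), a component of the super elongation complex, the glycosidase gene MYORG (-0.70 ± 0.10), the receptor tyrosine phosphatase gene PTPRS (-0.65 ± 0.07), the co-repressor gene TLE2 (-0.63 ± 0.11) and OXCT1 (-0.57 ± 0.09), an enzyme of ketone body use. Among rises at that level in the authors' deposited table, TIMM13, a mitochondrial import chaperone gene, came first (0.67 ± 0.09, adjusted p = 4.68e-11). PRLR, the prolactin receptor gene, rose by 0.56 ± 0.04 from a high mean normalized count of 3294 (adjusted p = 1.01e-44) in the authors' deposited table. The next rises at that level in the authors' deposited table included those of RUSC2 (0.61 ± 0.13), LMBRD2 (0.60 ± 0.10), CRACR2B (0.49 ± 0.12), REEP6 (0.45 ± 0.09), the tight junction gene TJP3 (0.43 ± 0.06) and MTMR12 (0.43 ± 0.08).

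In the authors' deposited table for MCF7, 83 of 359 assigned rows with an adjusted p passed the threshold, 38 higher and 45 lower with the PTEN shRNA. All rows of the authors' deposited table gave 1242 of 9812, 671 higher and 571 lower, and the balance turned to 87 higher and 167 lower with an absolute log2 fold change of at least 1. It also turned, to 490 higher and 718 lower, when the fold changes were centred on their median (0.057) and the scores recomputed, so which direction prevails in MCF7 is not settled. Of the assigned rows, 2 were higher and 9 lower at the larger size, and 23 higher and 57 lower with centring. Row labels with the largest rises at a mean normalized count of at least 100 were ELOVL2, DNAJC6, RUNX1T1, COL16A1, NUDT21, APBB2, AMFR and GSTM3, from 1.11 to 2.75 in the authors' deposited table, and the largest falls were those of CHRNA2 (-1.94), WASF3-AS1 (-1.71) and SLC39A8 (-1.70), none of them in a segment. With standard errors multiplied by the square root of 2, 38 assigned rows and 477 rows in all passed, and CRACR2B was no longer among them.

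**Figure D2:**
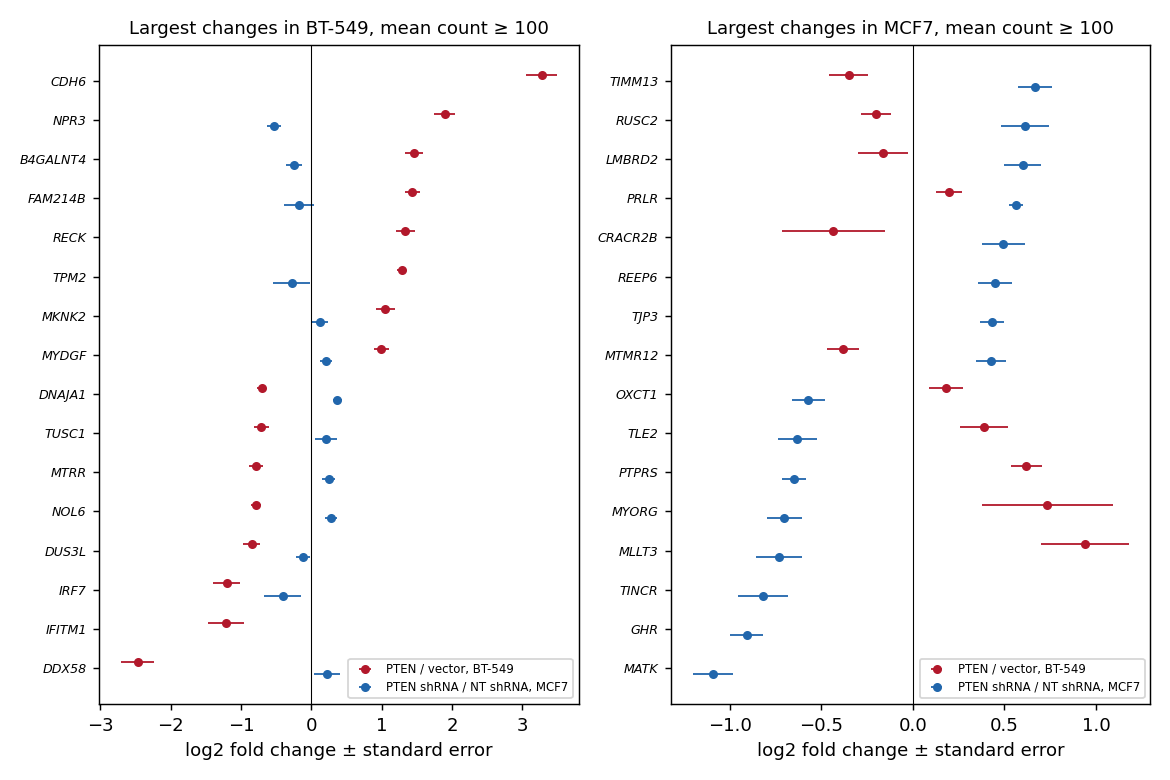
Log2 fold changes with standard errors from the authors' 2 deposited tables for the 8 largest rises and 8 largest falls among assigned rows with a mean normalized count of at least 100 in BT-549 (left) and in MCF7 (right), PTEN over vector in red and PTEN shRNA over non-targeting shRNA in blue. A point is left out where the row is absent or its mean normalized count is under 10; PTPRS lies at 0.62 in BT-549 and at -0.65 in MCF7.

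Gain and loss of PTEN are opposite manipulations, so rows called in both lines were compared by direction. Of 7913 rows with an adjusted p in both of the authors' deposited tables, 437 passed in both. Of these, 271 (62.0%) went opposite ways, against 49.8% from the margins (Fisher's exact test of direction, two-sided, p = 1.54e-07). Rows higher with PTEN in BT-549 and lower with the shRNA in MCF7 numbered 137 against 57.9 from independent lists (Fisher's exact test, two-sided, p = 6.04e-24), and the reverse numbered 134 against 67.6 (p = 5.90e-16). Rows higher in both numbered 105 against 72.6 (Fisher's exact test, p = 6.64e-05), and rows lower in both 61 against 53.9 (p = 0.296), which with centred fold changes and recomputed scores became 83 against 65.9 (p = 0.0249). At a mean normalized count of at least 100 in both tables lay 1334 of the 7913 rows, but 262 of the 437. Abundant rows can be called more readily in both tables and so raise each of these counts above that from independent lists. The test of direction among the 437 is less open to this. Genes are not independent replicates, and these p-values describe the tables. Among assigned rows, 26 of 37 went opposite ways (70.3%, Fisher's exact test of direction, p = 0.0210).

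Opposite changes of similar size were seen in the authors' deposited tables for PTPRS (0.62 ± 0.09 in BT-549, -0.65 ± 0.07 in MCF7), for C5orf51 (0.45 ± 0.10 and -0.45 ± 0.10) and for MTMR12 (-0.38 ± 0.09 and 0.43 ± 0.08). EEF2 (ENSG00000167658), the translation elongation factor gene and one of the most abundant assigned rows, was higher by 0.45 ± 0.10 with PTEN and at -0.56 ± 0.03 with the shRNA in the authors' deposited tables. The authors' deposited tables gave opposite changes also for NPR3 (1.89 ± 0.15 and -0.53 ± 0.10), OSMR, the oncostatin M receptor gene (0.91 ± 0.06 and -0.39 ± 0.13), TLE2 (0.39 ± 0.13 and -0.63 ± 0.11) and DNAJA1 (-0.70 ± 0.07 and 0.37 ± 0.07). The other 11 assigned rows went the same way in both. Ranked by the smaller of their 2 changes at a mean normalized count of at least 100 in both of the authors' deposited tables, the first were UHRF1, a factor of maintenance DNA methylation (-0.45 ± 0.08 and -0.40 ± 0.08), DAP (0.52 ± 0.11 and 0.32 ± 0.07), the stress gene GADD45B (-0.54 ± 0.13 and -0.30 ± 0.09) and BAG1 (-0.33 ± 0.11 and -0.28 ± 0.10). With standard errors multiplied by the square root of 2, BAG1 no longer passed in either line, OSMR and GADD45B no longer passed in MCF7, and TLE2 no longer passed in BT-549.

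**Figure D3:**
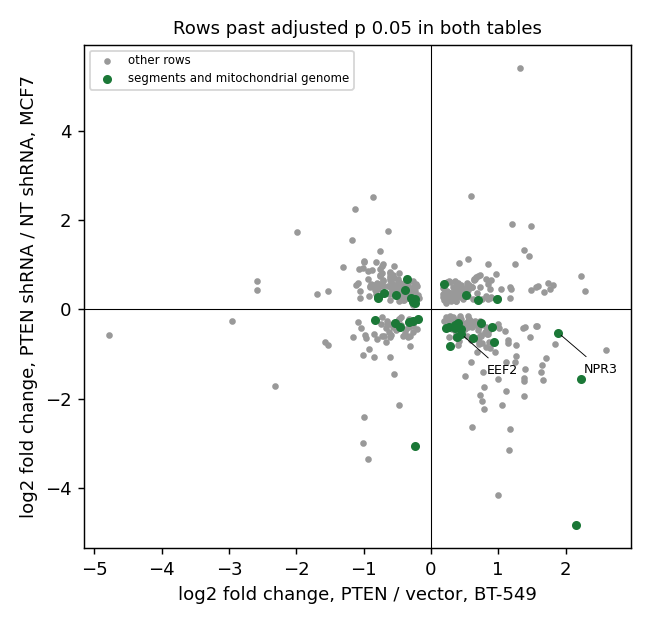
Log2 fold changes of the 437 rows past an adjusted p of 0.05 in both of the authors' deposited tables, BT-549 (PTEN over vector) on the x axis and MCF7 (PTEN shRNA over non-targeting shRNA) on the y axis, with the 37 assigned rows in green. The upper left and lower right quadrants together hold 271 rows.

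All 15 mitochondrially encoded rRNA and protein transcripts were measured in both lines. In the authors' deposited table for BT-549, 5 were lower and 1 higher with PTEN. They included MT-RNR2 (-0.37 ± 0.09, adjusted p = 0.000856) and MT-ND2 (-0.32 ± 0.06, adjusted p = 3.04e-06), while MT-CYB was higher (0.20 ± 0.07, adjusted p = 0.0251). With the PTEN shRNA in MCF7, 4 were lower and 4 higher in the authors' deposited table. MT-ND4 (-0.39 ± 0.04) and MT-ND4L (-0.31 ± 0.06), which share a transcript, were lower, as was MT-ND1 (-0.21 ± 0.03), and MT-RNR1 (0.16 ± 0.04) was higher in the authors' deposited table. MT-RNR2 was at 0.00 ± 0.04 in MCF7 in the authors' deposited table. As a list these transcripts did not pass in either line (cameraPR, adjusted p = 0.683 in BT-549 and 0.532 in MCF7). These small changes depend on the centre of the fold changes. With centring and recomputed scores, 3 were lower and 1 higher in BT-549, 6 were lower and 0 higher in MCF7, and the list passed as lower in MCF7 (cameraPR, adjusted p = 0.000282). Subtracting a constant moves the scores of rows with small standard errors, such as these, more than those of most rows. That pass is therefore no evidence of a change of these transcripts. With log2 fold changes in place of the scores, where a constant makes no difference, the list did not pass in MCF7 (cameraPR, adjusted p = 0.978). With standard errors multiplied by the square root of 2, MT-RNR2, MT-RNR1, MT-ND1, MT-CO1 and MT-CYB no longer passed in BT-549, which left only MT-ND2. In MCF7 none of the higher transcripts (MT-RNR1, MT-CO2, MT-ATP6 and MT-CO3) passed any longer, nor did MT-ND3. That left MT-ND1, MT-ND4 and MT-ND4L, all lower. With the scores as deposited and adjusted over the list alone, 2 were higher and 6 lower in BT-549, and 4 were higher and 4 lower in MCF7.

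With the scores as deposited, no gene list passed cameraPR at an adjusted p under 0.05, with 29 lists measured in BT-549 and 31 in MCF7. At an unadjusted p under 0.05 there were 4 lists in BT-549 and 3 in MCF7. The lowest adjusted p was 0.0661 in BT-549, for FOXO targets, and 0.109 in MCF7, for PI3K-AKT pathway components. Of the list members measured, 11 of 282 lay in the segments in BT-549 and 10 of 371 in MCF7, so outside the mitochondrial list the tests rest largely on row labels. The members inside that are given here are examples, and others, among them CA9 and TEK, are left out. HMGCS1, an enzyme gene of the mevalonate pathway, was higher with PTEN in BT-549 (0.78 ± 0.09, adjusted p = 1.16e-17) and at 0.16 ± 0.08 in MCF7 (adjusted p = 0.242) in the authors' deposited tables. RICTOR, a subunit of the kinase complex mTORC2, was higher in BT-549 (0.27 ± 0.08, adjusted p = 0.00337), as was the RNA polymerase II subunit gene POLR2L (0.35 ± 0.10, adjusted p = 0.00230), in the authors' deposited table. In MCF7 the authors' deposited table had RICTOR at 0.09 ± 0.08 (adjusted p = 0.620) and POLR2L at 0.22 ± 0.13 (adjusted p = 0.293). Neither passed in BT-549 with standard errors multiplied by the square root of 2. RPS6 was at 0.09 ± 0.06 in BT-549 (adjusted p = 0.310) and at -0.20 ± 0.08 in MCF7 (adjusted p = 0.0520) in the authors' deposited tables.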

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

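The effects of the 8 assigned genes named for opposite changes were compared after reversing the sign in MCF7, so that both stand for more PTEN over less, with a Wald test of the difference adjusted over the 8 genes. In 3 of them the size of the effect differed between the lines. The difference, BT-549 minus MCF7 on the log2 scale, was 1.36 for NPR3, 0.514 for OSMR and -0.332 for DNAJA1. The highest of the 3 adjusted p-values was 0.00113, and with standard errors multiplied by the square root of 2 it was 0.0339. The genes were chosen because they passed in both tables, gain in one line and loss in the other is not one treatment, and no explanation was tested.

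Many genes used by every cell had few or no reads, and of the tests of this pattern only that on the short arm of chromosome 18 was set before its result was seen. The labels name hg19, while 92.3% and 93.5% of the versioned gene identifiers are those of an annotation on GRCh38, so a candidate explanation is that reads aligned to one assembly were counted with gene positions of the other. Positions on the short arm of chromosome 18 hardly differ between these assemblies, and 40 of its 66 protein-coding genes (60.6%, exact 95% interval 47.8 to 72.4) reached the level, against 17 of 203 (8.37%) on the rest of that chromosome. Counting on the opposite strand is argued against by MT-ND6, the only protein gene on the light strand, since the median of the other mitochondrial protein genes was at least 14.01 times its level in both tables. Too few reads is argued against by ribosomal protein genes, which reached the level no more often (20.8%) than all protein-coding genes (21.3%); a search for 1 shift per window that places ubiquitous genes on high rows did not decide, with 54 placed on the same strand against 50 on the opposite one in a first version and 23 against 26 in a second, so the mixed assemblies remain a hypothesis that an hg19 annotation, not used here, would test.

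The MCF7 table averaged 8 columns for 4 samples, and all tests of this pattern were chosen after the units had been seen. A chance structure is argued against, since 100% of the distinct values of 3 reads were sums of the 8 units. One model over all 8 samples of the series, which would give a row the same mean in both tables, is argued against, since 0% of the shared rows had mean normalized counts equal to within a relative difference of 1e-06. The series design names 2 technical replicates per biological replicate, so technical runs entered as separate columns may account for the 8. The units did not form clearly separate pairs, with a largest gap within pairs of 0.573 times the smallest gap between pairs, which missed the bound set for close pairs; runs of one library need not have similar depth, so that bound was wrong for ruling them out, what the 8 columns are stays open, and no biological explanation was tested.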

How the results depend on the processing

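No paired analysis was possible because the tables hold no values per sample. For the same reason the settings foreseen with another tool or pseudocount, another normalization, each replicate left out, a replicate block or an estimated correlation were not run, and PTEN in BT-549 had no row to centre. Under the settings fixed before the data were examined, the BT-549 count of 2146 (1123 higher, 1023 lower) became 699 (400 and 299) with an absolute log2 fold change of at least 1 and 1318 (703 and 615) with the Benjamini-Yekutieli adjustment. The MCF7 count of 1242 (671 and 571) became 254 (87 and 167) and 725 (394 and 331), which turned the balance of direction at the larger fold change, and an adjusted p under 0.01 left 379 lower rows. A filter at a mean normalized count of 10 and no filter moved no count of either line by more than 1.5 times. Centring, planned for direction counts with the calls as deposited, changed none of them. The rows called in both lines went from 437 to 258 at an adjusted p under 0.01, 31 with an absolute log2 fold change of at least 1, and 262 at a mean normalized count of at least 100. The opposite share was above that of the margins in each, but with the fold change threshold Fisher's exact test no longer passed (71.0%, p = 0.320, with 31 rows left). No list passed with a preset correlation of 0.05, ranks or log2 fold changes, and at a mean normalized count of at least 100 only 2 lists in BT-549 and 3 in MCF7 could be tested, none of which passed. Centring left the PTEN row of MCF7 at 1.55.

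Other alternatives were chosen after seeing the data. With standard errors multiplied by the square root of 2, BT-549 kept a count of 984 (530 higher, 454 lower) and MCF7 one of 477 (255 and 222). With scores recomputed from centred fold changes, BT-549 had 2128 (1144 and 984) and MCF7 1208 (490 and 718), assigned rows 136 (74 and 62) and 80 (23 and 57), and 431 rows were called in both (62.9% opposite), 39 of them assigned (69.2%). The list of mitochondrially encoded transcripts then passed as lower in MCF7, the only 1 to do so. Centring moves the scores of these abundant rows, with their small standard errors, more than those of most rows, so the pass is no evidence of a change. No biological cause was tested. Assigned rows only gave 140 (73 and 67) in BT-549, 83 (38 and 45) in MCF7 and 37 called in both. Assigned rows in BT-549 numbered 30 (23 and 7) with an absolute log2 fold change of at least 1, 79 (42 and 37) with the larger standard errors and 57 (27 and 30) with the first segment rule, a level of 20 in both tables. In MCF7 the same 3 settings gave 11 (2 and 9), 38 (13 and 25) and 24 (12 and 12). Lower counts follow from fewer rows or larger errors by construction. Of 99 results for single genes or row labels given as called, 11 lost their call with the Benjamini-Yekutieli adjustment, 2 with centring and recomputed scores (MT-RNR1 and PLIN3 in MCF7) and 18 with the larger standard errors. None changed sign, but the adjustment and the larger standard errors leave fold changes as they are, and centring moves them little. The 18 were BAG1 and LIFR in both lines, TLE2, RICTOR, POLR2L, MT-RNR2, MT-CYB, PRLR, POLR1E and RPL36 in BT-549, and OSMR, GADD45B, CRACR2B, MT-RNR1, PLIN3 and PLIN4 in MCF7. Mitochondrial and ribosomal protein rows that are named elsewhere only for losing their call are not among the 99.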

Other observations

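The short arm of chromosome 18 lay outside the runs that the rule for segments took, so its rows are given by label only. The share of its protein-coding genes at the level (60.6%) was nevertheless close to that in the segments (62.7%). The latter includes genes by which the segments were chosen, and was 59.1% for those that the rule did not use. In the authors' deposited table for BT-549, 16 of 53 of its rows with an adjusted p passed, 5 higher and 11 lower with PTEN. In MCF7 18 of 61 passed, 9 higher and 9 lower with the shRNA, which became 4 and 11 with centred fold changes and recomputed scores. The row labelled APCDD1 was at 5.91 ± 0.34 with PTEN in BT-549, and that labelled LDLRAD4 at -1.58 ± 0.15 with the shRNA in MCF7 in the authors' deposited tables. Rows labelled SEH1L (-0.69 ± 0.09 in BT-549) and RAB31 (0.28 ± 0.06 and 0.61 ± 0.05) also passed in the authors' deposited tables. These rows were chosen after their values were seen.

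Further groups of genes in the segments were put together only after their values had been seen, so their percentiles among 10000 sets of assigned rows matched on mean normalized count describe the tables and test nothing. In the authors' deposited table for MCF7, the perilipin genes PLIN3 (0.23 ± 0.08), PLIN4 (0.68 ± 0.16) and PLIN5 (0.79 ± 0.17), which coat lipid droplets, were all higher with the shRNA (median at percentile 99.9). Of the class I cytokine receptor genes in MCF7, GHR (-0.91 ± 0.09), LIFR (-0.39 ± 0.12) and OSMR (-0.39 ± 0.13) were lower and PRLR (0.56 ± 0.04) was higher in the authors' deposited table (median at percentile 0.94). GHR had a mean normalized count under 10 in BT-549, and the set there was OSMR, LIFR and PRLR, which were higher with PTEN, and IL7R, which was lower (-0.48 ± 0.09) in the authors' deposited table (median at percentile 92.6). The ribosome and RNA-processing genes NOL6 (-0.79 ± 0.07), BRIX1 (-0.44 ± 0.09), NSUN2 (-0.35 ± 0.07) and POLR1E (-0.26 ± 0.09) were lower with PTEN in BT-549 in the authors' deposited table (median at percentile 0.49), and in MCF7 at percentile 84.4. The median of the interferon-induced genes DDX58, IFITM1, IRF7 and IFITM3 stood at percentile 0 in BT-549; in MCF7, where IFITM1 had a mean normalized count under 10 and IFITM2 stood in its place, the median was at percentile 84.6. Calls of PLIN3, PLIN4, OSMR and LIFR in MCF7 and of LIFR, PRLR and POLR1E in BT-549 ended with standard errors multiplied by the square root of 2, and PLIN3 did not pass with centring and recomputed scores either.

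The 5 ribosomal protein genes of the segments and EEF2 all had positive fold changes with PTEN in BT-549 and negative ones with the shRNA in MCF7, and the tests of this pattern were chosen after it had been seen. In the authors' deposited tables RPL37 was at 0.40 ± 0.07 and -0.31 ± 0.04, and RPL36 at 0.22 ± 0.07 and -0.41 ± 0.05; 3 of the 6 rows passed in BT-549 and 5 in MCF7. The group's median was 0.22 in BT-549, at percentile 88.9 of matched sets, and -0.28 in MCF7, at percentile 0.05. By the bounds first set these values argued against a trend with abundance and against a hypothesis of coordinated change with PTEN level in both directions, but both readings were withdrawn after the result. The matched rows had a median mean normalized count of 1461 against 2589 in the group in BT-549, and of 883 against 3189 in MCF7, so the percentiles decide neither, and both stay open. With standard errors multiplied by the square root of 2, RPL36 did not pass in BT-549, and RPLP2 and RPS15 did not pass in MCF7.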
